A study of Mus musculus with 16 samples.

How the data were processed

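Total RNA was extracted from mouse liver tissue with TRIzol, and polyadenylated RNA was made into libraries from 200 ng of RNA and sequenced with a BGI protocol, per the labels' protocols. FastQC, HISAT2, SAMtools and StringTie are named with the mouse build mm10 in the submitters' processing notes. Their versions, settings and gene annotation, and the tool that made the counts, are not given in the sources used here. The deposited table gave 1 value per gene and library for 16 libraries, in a unit best described as signal: read counts of each gene that the authors had divided by 1 size factor per library. In all 16 libraries 100% of the values were whole numbers of reads within 0.01 read once multiplied by that factor, and the factors equalled median-of-ratios factors computed over the 16 libraries. Such scaling assumes that most genes do not change, so a change in total RNA per cell is not seen. Depth was 12562943 to 27110501 recovered reads per library. All columns matched a labelled sample.

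Of 16793 genes in the table, 16479 matched 1 gene of GENCODE M21, which uses the build GRCm38 (mm10), and 99.6% of these were protein coding. Another 314 had no match, and 24 names had been turned into dates, 2 of them occurring in 2 places. Coordinates, transcript length and GC content came from GENCODE M21. Whether the authors counted reads by strand, and how they treated reads shared by similar genes, is not given in the sources used here, so genes of the Mup, cytochrome P450, hemoglobin and serum amyloid families and overlapping genes are uncertain.

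Groups were taken from the labels: sham surgery, ovariectomy, empty vector and LCAT overexpression, with 4 libraries each. Ovariectomy was compared with sham surgery and LCAT overexpression with the empty vector, each from its own 8 libraries. The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, unless stated. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a trended and robust prior, for genes with a mean of at least 10 over the 8 libraries. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. A fold change on this scale understates the change of low genes. Lcat and Esr1 also had an exact two-sided permutation test, whose smallest p is 0.0286 with 4 against 4.

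The 37 lists, 24 of gene groups and 13 of cell type markers or sample checks, were tested with camera at a preset correlation of 0.01, with its variance trend on, adjusted over all lists; 700 of 717 entries were in the table. The same test was run with a correlation estimated per list. At the preset correlation, splits that mix the groups passed up to 22 lists in the surgery and 21 in the vector experiment. An adjusted p at the preset correlation alone therefore does not tell a group effect from other differences between libraries. The lists covered female-biased and male-biased liver genes, hormone signalling, lipoprotein handling, cholesterol, bile acid and fat synthesis, fatty acid oxidation, the cell cycle, tumour markers, NRF2 targets, pericentral, periportal and general hepatocyte genes, glycolysis, the respiratory chain, matrix, cytokines, interferon response, antigen presentation, acute phase, stress response, p53 targets and the circadian clock. Marker lists covered Kupffer cells, monocytes, T, NK and B cells, neutrophils, stellate and endothelial cells, cholangiocytes, adipocytes, erythroid and acinar cells, and Xist with Y-linked genes. Some genes were in more than 1 list.

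The text names Lcat and Esr1, and up to 8 genes in each direction with the largest change among those past the threshold, with a mean of at least 50 and no overlap between groups, leaving out immunoglobulin, T cell receptor and predicted genes. It also names the 3 members with the smallest p of each list that passed, and 1 member past the threshold of other lists. Some genes that these rules select are not reported here. Genes of the hypoxia list in the closing observations were chosen after their values were seen. For a gene with 0 reads in a group, the fold is a bound against 3 reads over the group, and with 1 to 3 reads a ratio with a 95% counting interval. Both effects were compared by correlation across genes against the 35 distinct splits of the vector libraries, by overlap with that of independent lists, and with fry, adjusted over its pair of sets.

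Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, rescaling by TMM, median of ratios or equal totals, all 16 libraries in one fit, the replicate number as a block, limma arrayWeights, no trend, a log2 fold change of at least 1, and leaving out each library. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads; 13 adjusted p-values after ovariectomy and 24 after LCAT were not given by DESeq2 and stayed missing. Chosen after the data were seen were fits on the end libraries alone, a fit with transcript length and GC content smoothed out of each library (splines with 4 degrees of freedom; for Lcat also either alone, and for the respiratory chain length alone), and list and set tests with equal totals. The procedure was tested on simulated reads with 200 changed genes and a seed of 1. After ovariectomy settings (13026 genes run), limma found 12.1%, 65.7% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 9 false among 124 calls. With LCAT settings (12909 genes run) it found 7.6%, 52.2% and 95.2%, with 2 false among 101. The simulated libraries were independent and far fewer genes changed than in the data, so these rates need not hold there. Permutation tests, tables and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.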

Results

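Messenger RNA was sequenced from liver tissue of mice in which primary liver cancer had been induced, taken at the end of the experiment. The 16 libraries formed 4 groups of 4. In the surgery experiment, female mice had sham surgery or ovariectomy, which removes the main source of circulating estrogen. In the vector experiment, the liver received an empty vector or overexpressed LCAT, lecithin-cholesterol acyltransferase, an enzyme that hepatocytes secrete and that esterifies the cholesterol of high-density lipoprotein. The deposited values were normalized read counts of 16793 genes, from which whole reads could be recovered. Recovered totals ran from 21428827 to 25850761 reads in the sham libraries and from 17782178 to 27110501 in the ovariectomy libraries. They ran from 14412808 to 20659336 with the empty vector and from 12562943 to 19248762 with LCAT. Means below are normalized read counts ± SD (n = 4 libraries per group), and changes are log2 fold changes on the log2(value + 1) scale. The p-values measure the spread between these samples, because the labels do not say that the libraries come from separate animals.

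In the sham and the ovariectomy group, libraries 2 and 3 lay between libraries 1 and 4. Across 627 genes that differed at least 2-fold between sham libraries 1 and 4, sham library 2 took a median share of 0.664 of library 1 (quartiles 0.596 to 0.734) and sham library 3 a share of 0.456 (0.386 to 0.516). The shares were 0.775 and 0.621 for ovariectomy libraries 2 and 3, across 388 genes. LCAT libraries 2 and 3 had shares of 0.409 and 0.383 across 1586 genes, whereas the empty vector libraries showed no such line. Pairs of empty vector libraries were the most alike of any group, differing by 2.13 to 4.46 times the counting variance. The lack of a line therefore does not show that these libraries are independent.

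The first comparison asked how loss of the ovaries changed gene expression in livers with induced cancer. After ovariectomy, Lcat fell from 5662 ± 61.9 to 3389 ± 241, a log2 fold change of -0.74 (SE 0.067, limma adjusted p = 0.000167). Genes of the cell cycle, of the interferon response and of cholesterol synthesis were higher, with list medians of 2.08, 1.32 and 0.92. Genes more active in female than in male liver were lower (median -1.34), as were periportal genes (-0.89) and general hepatocyte genes (-0.47). Of 13059 genes tested, 5170 changed at an adjusted p below 0.05, 2484 of them higher and 2686 lower. Whether tumour or other liver tissue was sampled, and whether alike in both surgery groups, is not given in the sources used here. A change in the share of tumour tissue therefore cannot be told apart from a change within cells.

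Lcat lies on chromosome 8 of mm10 from 105939551 to 105943382, on the minus strand. Its values were separate between the sham and the ovariectomy group (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). Esr1, the gene of estrogen receptor alpha, lies on chromosome 10 from 4611593 to 5005614, on the plus strand. Its means were 320.0 ± 164 after sham surgery and 315 ± 156 after ovariectomy, a log2 fold change of -0.04 (SE 0.61) with an adjusted p of 0.965 and an exact permutation p of 0.914. Its libraries varied widely, with 328, 350, 102 and 500.1 in the sham group and 436, 339.7, 397 and 89.5 after ovariectomy, and the 95% interval of the change ran from -1.43 to 1.36. With library totals set equal, the log2 fold change was 0.20, and it ran from -0.52 to 0.49 when single libraries were left out. Over 23 alternatives it ran from -1.03 to 0.69 and passed in 0 of them.

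**Figure D1:**
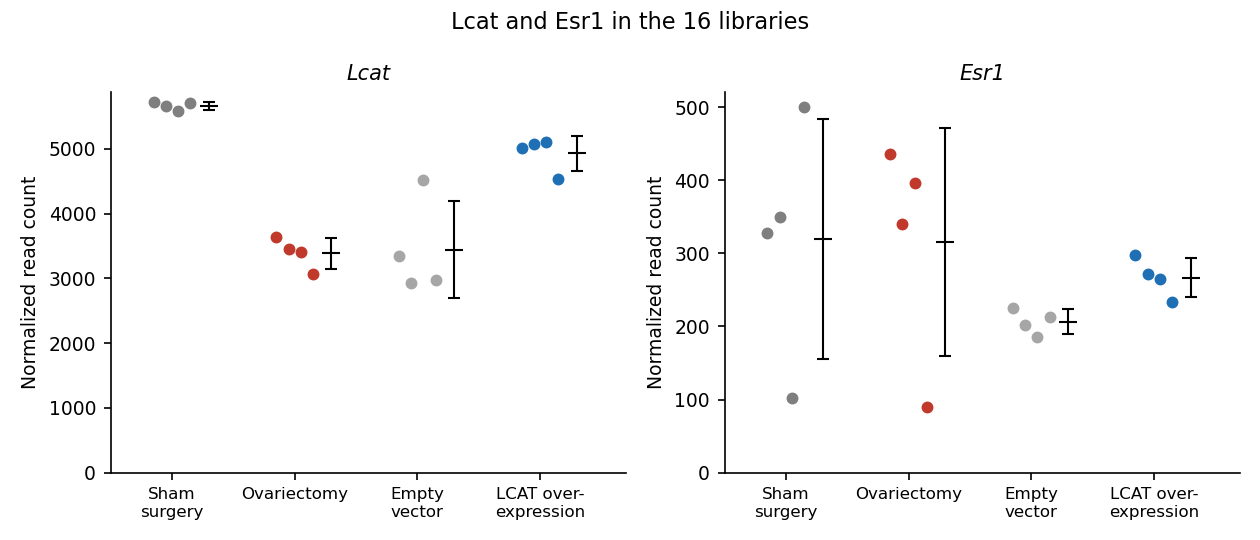
Normalized read counts of Lcat and Esr1 in each library of the sham, ovariectomy, empty vector and LCAT groups, with the mean and SD of each group. Lcat averaged 5662 after sham surgery and 3389 after ovariectomy, and 3444 with the empty vector and 4931 with LCAT overexpression.

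The genes with the largest increases after ovariectomy included the cytokine gene Il6 (1.79 ± 2.58 to 278 ± 198, log2 fold change 6.29, SE 1.13) and Msln, which encodes the cell surface protein mesothelin (7.49 ± 9.43 to 142 ± 12.6). The mitotic genes Plk1 (4.67), Tpx2 (4.46), Cdc20 (4.30) and Hmmr (4.26) were also among them, with Spata20 (4.51) and the homeobox gene Lhx3 (4.23). Il6 was 419, 440, 240 and 13.8 in ovariectomy libraries 1 to 4, against up to 5.48 after sham surgery. Spata20 (51.1) and Lhx3 (26.6) were also lowest in ovariectomy library 4, while Msln and the mitotic genes were highest there. Among the large decreases was that of the cytochrome P450 gene Cyp2b10 (293 ± 38.7 to 17.6 ± 8.22). Further decreases were in Myom3 (-3.64), Wfikkn1 (-3.50), the serine dehydratase gene Sds (-3.31), Map2k6 (-3.21), the sulfotransferase gene Sult2a1 (-3.14) and Mfsd2a (-2.77). Wfikkn1 was 14.6 in sham library 4, against up to 13.2 after ovariectomy. The 4 ovariectomy values lay outside the range of the 4 sham values, which the naming rule asks for, in 5090 genes, 39.0% of those tested, where chance gives 2.86%.

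Genes that differ between female and male liver changed in both sets. Of 27 female-biased genes, 20 fell and 1 rose (camera adjusted p = 5.72e-09), among them the transcription factor gene Cux2, from 235 ± 20.3 to 42.6 ± 5.92, with Nipal1 (-1.64) and Cyp3a44 (-1.61). Of 25 male-biased genes, 11 rose and 3 fell (adjusted p = 0.021, and adjusted p = 0.398 with an estimated correlation). Among them were the major urinary protein genes Mup12 (83.8 ± 33.7 to 635 ± 353) and Mup1 (94.7 ± 36.7 to 702 ± 395) and Selenbp2 (0.60). Mup12 and Mup1 are near-identical copies, so reads of the copies cannot be told apart with confidence. Of 18 genes of sex hormone, growth hormone and prolactin signalling, 10 fell and 0 rose (median -0.83, adjusted p = 0.000268). They included the growth factor gene Igf1 (8698 ± 824 to 3597 ± 157), its binding protein gene Igfbp1 (-1.35) and Socs2 (-2.21), a growth hormone-induced inhibitor. The counts adjusted over the list alone were the same for these 3 lists. Without sham library 4 the male-biased list did not pass (adjusted p = 0.089).

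In lipid metabolism, 22 of 23 cholesterol synthesis genes rose and 0 fell (22 and 0 adjusted over the list alone; adjusted p = 8.4e-13). Fdps rose from 2809 ± 138 to 6554 ± 238 (log2 fold change 1.22, SE 0.063), with Mvk (1.25) and Fdft1 (1.10). Of 27 genes of fatty acid oxidation and targets of the lipid sensor PPARA, 21 fell and 2 rose (23 and 3 adjusted over the list alone; median -0.66, and -0.42 with equal library totals, adjusted p = 5.25e-07, and adjusted p = 0.238 with an estimated correlation). Cyp4a10 (-2.35), Cyp4a14 (-2.08) and Acadvl (-0.66) were among those that fell. The lists of lipoprotein handling (median -0.15, adjusted p = 0.0438, and adjusted p = 0.142 with an estimated correlation) and bile acid synthesis and transport (median -0.17, adjusted p = 0.0171, and adjusted p = 0.327 with an estimated correlation) were lower as deposited, but their medians were 0.09 and 0.07 with equal library totals. In the former, 11 of 29 fell and 5 rose (12 and 6 adjusted over the list alone). These included Apoa4 (468572 ± 35704 to 131047 ± 10571) and Apoc3 (-1.0). That list did not pass without sham library 1 (adjusted p = 0.0566), sham library 4 (0.0967) or ovariectomy library 2 (0.0598). In the latter, 9 of 22 fell and 2 rose by either adjustment, including the bile acid transporter gene Slc10a1 (2474 ± 107 to 570.3 ± 78), Cyp2c70 (-0.76) and Cyp27a1 (-1.16). Of 28 genes of fat synthesis and storage, 12 fell and 3 rose (12 and 4 adjusted over the list alone), among them Plin4 (-1.99), and the list did not pass (median -0.19, and 0.05 with equal library totals, adjusted p = 0.0669); it passed without sham library 1 (adjusted p = 0.0468) or ovariectomy library 4 (0.00979).

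All 29 cell cycle genes tested rose, by either adjustment (median 2.08, adjusted p = 3.58e-16). The proliferation marker Mki67 went from 80.6 ± 22 to 717 ± 218, with Aurkb (3.13) and Cdk1 (2.07). Of 25 liver tumour and oncofetal markers, 16 rose and 2 fell (16 and 3 adjusted over the list alone; adjusted p = 0.000171). Among them were Spink1 (1.68), Golm1 (1.07) and Prom1 (0.58). Targets of the oxidative stress factor NRF2 rose in 12 of 24 genes and fell in 0, by either adjustment (adjusted p = 0.00104, and adjusted p = 0.434 with an estimated correlation), among them Slc7a11 (489.7 ± 181 to 2090.2 ± 303), G6pdx (1.18) and Txnrd1 (0.92). In the unfolded protein and integrated stress response, 10 of 20 genes rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.0236, and adjusted p = 0.464 with an estimated correlation, and 0.12 without sham library 4), with Creld2 (1.44), Sdf2l1 (1.46) and Pdia4 (0.95). Of 18 p53 targets, 6 rose and 5 fell (7 and 5 adjusted over the list alone), Phlda3 among the former (1.42), and the list did not pass (median 0.27, and 0.51 with equal library totals, where 8 were higher and 1 lower, adjusted p = 0.141).

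Hepatocyte genes were lower. Of 24 general hepatocyte genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.47, and -0.22 with equal library totals, adjusted p = 1.03e-06). These included Hpd (5395 ± 220.1 to 1371 ± 226) and Apoh (-0.92). Of 21 periportal and gluconeogenic genes, 16 fell and 1 rose, by either adjustment (adjusted p = 7.15e-08), among them Pck1, which controls the first committed step of gluconeogenesis (49274 ± 8328 to 7177 ± 439.9), the urea cycle gene Ass1 (-1.58) and Igf1. The Wnt target and pericentral list did not pass (median -0.01, and 0.23 with equal library totals, adjusted p = 0.416), with 1 of 19 genes higher and 5 lower by either adjustment, Cyp2e1 among them (-0.98, a call lost in a fit of all 16 libraries). Glycolysis and glucose transport genes fell in 9 of 23 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.32, adjusted p = 0.0266, and adjusted p = 0.377 with an estimated correlation, and 0.0972 without sham library 4). With equal totals, 6 were lower and 4 higher (median -0.08). Among those lower as deposited were Gpi1 (-0.87), Slc2a2 (-1.31) and Pgk1 (-0.55). Of 27 respiratory chain genes, 19 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.41, adjusted p = 5.55e-07, and adjusted p = 0.377 with an estimated correlation). These included Ndufv1 (-0.45), Ndufb9 (-0.54) and Ndufa1 (-0.46), of which Ndufv1 and Ndufa1 lost their calls with equal library totals. With equal totals, 3 of the list were lower and 1 higher (median -0.17). Circadian clock genes fell in 9 of 20 cases and rose in 0, by either adjustment (adjusted p = 0.00298, and adjusted p = 0.238 with an estimated correlation), with Cry2 (-2.17) and Bhlhe40 (-1.0). Beside these, liver endothelial markers fell in 5 of 12 cases and rose in 0, by either adjustment (median -0.40, and -0.16 with equal library totals, adjusted p = 0.00266, and adjusted p = 0.054 with an estimated correlation). Among them were Stab2 (-0.75), Lyve1 (-1.10) and Oit3 (-0.60, lost in a fit of all 16 libraries). Without sham library 4, 8 of these markers were lower, and 9 with length and GC content smoothed out (median -0.52).

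Immune and matrix genes were higher. In the interferon response, 21 of 24 genes rose and 0 fell (23 and 0 adjusted over the list alone; adjusted p = 1.3e-12), with Isg15, a ubiquitin-like interferon-induced protein, going from 103 ± 16.3 to 575 ± 22.6, and Ifit1 (2.61) and Ifi44 (2.15). Of 15 antigen presentation genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone; adjusted p = 0.000115, and adjusted p = 0.12 with an estimated correlation). These included Psmb8 (0.68), Cd74 (0.84) and H2-Eb1 (1.33). Of 19 cytokine and chemokine genes, 9 rose and 0 fell by either adjustment (adjusted p = 0.00567, and adjusted p = 0.204 with an estimated correlation), with Cxcl13 (1.90), Cxcl9 (1.71) and Tlr2 (0.87). The acute phase list had 9 of 24 higher and 1 lower by either adjustment (adjusted p = 0.00518, and adjusted p = 0.526 with an estimated correlation), with the serum amyloid genes Saa2 (958 ± 288 to 6014 ± 2894) and Saa3 (0.99), while Lbp fell by 0.77. Without ovariectomy library 4, 19 of the acute phase genes were higher. Of 28 extracellular matrix and fibrosis genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone; adjusted p = 1.5e-07, and adjusted p = 0.103 with an estimated correlation), among them Acta2, a marker of activated stellate cells (169 ± 23.6 to 620.2 ± 126), Lum (1.21) and Col5a2 (1.23).

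Marker lists of blood, immune and bile duct cells mostly did not pass. Medians and adjusted p-values were -0.15 and 0.638 for Kupffer cells (a median of 0.09 with equal library totals), 0.01 and 0.492 for monocytes, 2.09 and 0.0675 for T cells, 0.65 and 0.263 for NK cells, 2.26 and 0.0515 for B cells, and -0.40 and 0.692 for neutrophils. They were 0.37 and 0.0636 for stellate cells, 0.86 and 0.103 for cholangiocytes, -1.07 and 0.174 for adipocytes and 0.12 and 0.638 for the single pancreatic gene tested. With equal totals the medians were 0.25 for monocytes, -0.17 for neutrophils, 0.61 for stellate cells and 0.36 for the pancreatic gene. Of the markers listed, 3 of 12 were tested for T cells, 2 of 11 for NK cells and 2 of 11 for B cells. Tested were also 2 of 7 adipocyte and 1 of 10 pancreatic markers. The medians of these lists do not stand for all their markers. Cd4 averaged 3.69 after sham surgery and 18.3 after ovariectomy, against a minimum mean of 10. Adjusted over the list alone, 1 of 12 Kupffer markers were higher and 3 lower, 4 and 2 of 11 for monocytes, 2 and 0 of 3 for T cells, 1 and 0 of 2 for NK cells, 2 and 0 of 2 for B cells and 2 and 3 of 8 for neutrophils. They were 7 and 2 of 12 for stellate cells, 4 and 1 of 9 for cholangiocytes and 0 and 1 of 2 for adipocytes, the same as over all genes except for 2 lower neutrophil markers. Single markers in these lists passed, including Mpeg1 (0.98), Itgax (1.37), Cd4 (2.09), Klrb1c (0.92), Jchain (2.58), Csf3r (0.92), Spp1 (1.96) and Cidec (-1.53). Erythroid markers fell in 3 of 6 cases and rose in 0, by either adjustment (median -1.47, adjusted p = 0.0438, and adjusted p = 0.473 with an estimated correlation), namely the hemoglobin genes Hba-a1 (-1.57), Hba-a2 (-1.55) and Hbb-bt (-1.39), which share sequence and varied widely between sham libraries. That list did not pass without sham library 3 (adjusted p = 0.0617), sham library 4 (0.122), ovariectomy library 1 (0.0617) or ovariectomy library 2 (0.0568). Without sham library 1, 6 of its genes were lower, and 0 without any of sham libraries 2 and 3 and ovariectomy libraries 1, 2 and 3. The calls of Hba-a1 and Hba-a2 were lost without any of sham libraries 2 and 3 and ovariectomy libraries 1, 2 and 3 (adjusted p from 0.0622 to 0.0731), and that of Hbb-bt without any library but sham 1 (0.0599 to 0.11). All 3 calls were also lost with equal library totals and with the end libraries, and that of Hbb-bt with no filter, TMM rescaling or no trend. The B cell list passed without sham library 1 (0.0468), sham library 2 (0.0402) or ovariectomy library 3 (0.0491), and the stellate list without ovariectomy library 3 (0.0491).

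**Figure D2:**
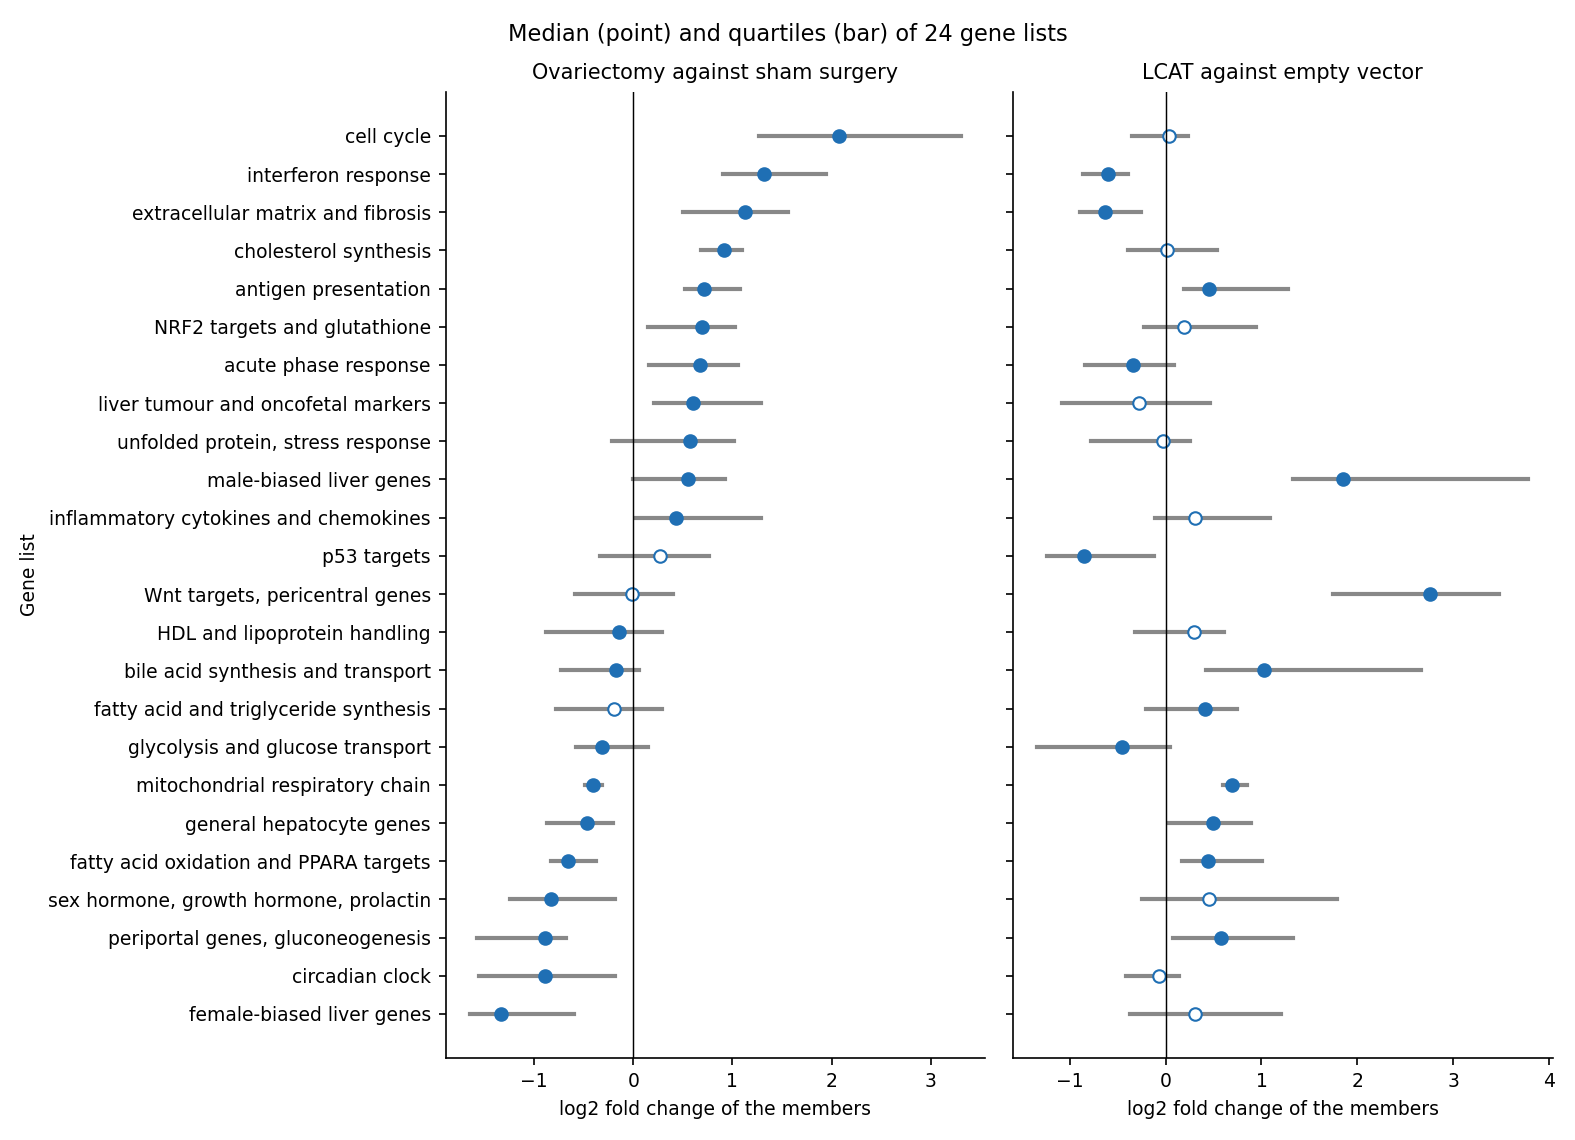
Median log2 fold change of each gene list after ovariectomy and after LCAT overexpression, with bars from the lower to the upper quartile of the members; filled points passed camera at an adjusted p below 0.05 and open points did not. The cell cycle median was 2.08 after ovariectomy and 0.03 after LCAT overexpression, and the Wnt target and pericentral median was -0.01 and 2.76; with equal library totals the cell cycle median after LCAT was -0.15 and the Wnt median after ovariectomy 0.23.

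With library totals set equal, the median of all genes shifted by 0.24 and 78.6% of 5650 called genes were higher, against 48.0% as deposited. Smoothing out length and GC content moved the balance the other way, with 36.9% of 5346 called genes higher. With libraries 1 and 4 of each group alone, limma called 0 genes (1688 at an unadjusted p below 0.05, and 0 by edgeR), while 21 of the 23 lists still passed. The lipoprotein (adjusted p = 0.0584) and erythroid (0.0691) lists did not pass there, and the B cell list did (0.0376). The 5158 genes called with all libraries and tested again kept the sign of their change. They were picked in a fit that held these same libraries, so the kept sign is no separate support. With length and GC content smoothed out, the lipoprotein (0.0818) and erythroid (0.0884) lists did not pass, the B cell list did (0.031), and the bile acid median was -0.28. With a mean of at least 50, the lipoprotein (0.0863), glycolysis (0.0575) and erythroid (0.0722) lists did not pass and the stellate list did (0.0436). The lipoprotein list did not pass with the replicate block (0.0713). With equal totals the male-biased (0.0695), acute phase (0.0623) and stress response (0.0778) lists did not pass, and the fat synthesis list did (0.00539).

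The other comparison asked which liver genes differ when LCAT is overexpressed. Livers with LCAT overexpression had higher Lcat, from 3444 ± 742 to 4931 ± 269.7 (log2 fold change 0.54, SE 0.14, limma adjusted p = 0.0168). Wnt target and pericentral genes (median 2.76), male-biased liver genes (1.85) and bile acid genes (1.03) were higher, and so were respiratory chain genes (0.69). Targets of p53 (-0.86), matrix genes (-0.63) and glycolysis genes (-0.45) were lower. None of these 7 lists passed with an estimated correlation (adjusted p from 0.0805 to 0.317). Of 13095 genes tested, 5332 changed, 2651 higher and 2681 lower.

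Single Lcat values were 3348, 2926, 4521 and 2980.1 in the empty vector libraries and 5014, 5074, 5106 and 4531 with LCAT (exact permutation p = 0.0286). The change was 0.13 (SE 0.15, adjusted p = 0.517) after transcript length and GC content were smoothed out of each library, and 0.35 (adjusted p = 0.0679) with equal library totals. It was 0.47 (adjusted p = 0.0522) without empty vector library 2 and 0.48 (0.0527) without library 4; over 23 alternatives the adjusted p ran from 0.00101 to 0.517. Whether transcripts of the introduced gene map to mouse Lcat is not given in the sources used here. Esr1 rose from 206 ± 16.9 to 267 ± 26.3, a log2 fold change of 0.37 (SE 0.11, adjusted p = 0.0277, exact permutation p = 0.0286). The Esr1 call was lost without any of empty vector libraries 2, 3 and 4 or LCAT libraries 2 and 3 (adjusted p from 0.0594 to 0.0713). It was also lost with equal library totals (log2 fold change 0.18, adjusted p = 0.164), a fit of all 16 libraries (0.542), the replicate block (0.0543) and the end libraries (0.168). The Esr1 call passed in 14 of 23 alternatives, that with length and GC content smoothed out among them. Over the 23 the change ran from 0.18 to 0.71 and the adjusted p from 0.0035 to 0.542.

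Among the largest increases, Wfdc18 had 0 reads in the empty vector group and averaged 213 ± 114 with LCAT, at least 285-fold higher against a floor of 3 reads over the group. Others were Gabrp (6.67), the transporter gene Slc22a28 (6.64), Tesc (6.02), the water channel gene Aqp5 (5.70), the macrophage receptor gene Marco (5.40), Hsd3b5 (5.19) and Elovl3 (5.11). In each of these genes LCAT library 1 had the lowest LCAT value. Marco was 7.78 there, against 184 to 300 in the other LCAT libraries and up to 6.14 with the empty vector. With the end libraries the limma calls of Marco (adjusted p = 0.113), Hsd3b5 (0.0699) and Elovl3 (0.0536) were lost. Unc13c, Vgf and Arhgap40 had 0 reads with LCAT. They averaged 1087 ± 63.8, 291 ± 99.6 and 107 ± 20.3 in the empty vector group, at least 1143-fold, 306-fold and 112-fold higher than in the LCAT group. Whether tumour or other liver tissue was sampled, and whether alike in both groups, is not given in the sources used here. The olfactory receptor gene Olfr815 went from 101.3 ± 16.6 to 2 reads in all LCAT libraries, a ratio of 159.9 with a 95% counting interval of 44.3 to 1321, where the interval and the floors cover counting error only. Xlr3b (-6.50), the guanylate cyclase gene Gucy2c (-6.48), Areg, which encodes the growth factor amphiregulin (229 ± 21.8 to 4.70 ± 4.63), and Spata20 (-5.64) also fell. Groups did not overlap in 5304 genes, 40.5% of those tested, where chance gives 2.86%.

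Hepatocyte genes were higher with LCAT. Of 20 Wnt target and pericentral genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 3.46e-08, and adjusted p = 0.229 with an estimated correlation). Among them were the drug-metabolizing enzyme gene Cyp1a2 (616 ± 154 to 4579 ± 479), the ammonia transporter gene Rhbg (16.2 ± 6.34 to 197 ± 28.6) and the Wnt inhibitor gene Notum (4.13). Of 21 periportal and gluconeogenic genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.00297, and adjusted p = 0.317 with an estimated correlation), with Otc (1.69) and Fbp1 (1.33) higher and Cdh1 lower (-1.11). General hepatocyte genes rose in 15 of 24 cases and fell in 0, by either adjustment (median 0.49, 0.30 with equal library totals and 0.28 with length and GC content smoothed out, adjusted p = 0.0002, and adjusted p = 0.208 with an estimated correlation). These included Hpd (703 ± 306 to 11437 ± 3254) and Ces3a (2.52). Male-biased genes rose in 29 of 30 cases and fell in 0, by either adjustment (adjusted p = 1.52e-14, and adjusted p = 0.229 with an estimated correlation). Among them were Mup20 (70033 ± 3578 to 238975 ± 17191), Cyp2d9 (1.72) and Cyp2u1 (2.02). Mup20 and Cyp2d9 belong to families of similar genes that can share reads. Female-biased genes did not pass as a list (median 0.31, 0.13 with equal library totals and 0.13 with length and GC content smoothed out, adjusted p = 0.232), with 7 of 20 higher and 4 lower (7 and 5 adjusted over the list alone). Sult2a1 had 0 reads in the empty vector group and 34.5 ± 15.5 with LCAT, at least 46.2-fold higher. The sex hormone and growth hormone list had 10 of 18 higher and 2 lower (10 and 3 adjusted over the list alone; median 0.45, adjusted p = 0.0531), with Igfals (184 ± 18 to 867 ± 75). It passed without empty vector library 1 (adjusted p = 0.0424), 2 (0.0447) or 4 (0.0384). It also passed with length and GC content smoothed out (median 0.58, adjusted p = 0.00494), with equal library totals (0.26, 0.0209) and with a mean of at least 50 (0.0474).

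Bile acid genes rose in 15 of 22 cases and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 8.45e-06, and adjusted p = 0.0805 with an estimated correlation), with Slc10a1 going from 435 ± 106 to 3455 ± 517, Amacr (1.19) and Baat (1.30). Of 27 fatty acid oxidation genes, 16 rose and 0 fell (16 and 2 adjusted over the list alone; median 0.44, and 0.26 with equal library totals, adjusted p = 0.000109, and adjusted p = 0.208 with an estimated correlation). These included Acaa1b (5043 ± 263 to 15501 ± 1357), Fabp1 (1.15) and Acaa2 (0.91). Fat synthesis and storage genes rose in 14 of 28 cases and fell in 4 (14 and 5 adjusted over the list alone; median 0.41, 0.23 with equal library totals and 0.19 with length and GC content smoothed out, adjusted p = 0.0286, and adjusted p = 0.229 with an estimated correlation, and 0.0672 without LCAT library 4), with Elovl6 (1.31), Me1 (1.13) and Fitm1 (2.69). Lipoprotein handling genes did not pass as a list (median 0.29, 0.11 with equal library totals and 0.09 with length and GC content smoothed out, adjusted p = 0.393), with 9 of 29 higher and 7 lower (10 and 7 adjusted over the list alone), Pon1 among the former (194 ± 64.2 to 3272 ± 1341). With equal totals 5 were higher and 9 lower. Cholesterol synthesis genes went both ways, with 7 of 23 higher and 9 lower by either adjustment (median 0.02, and -0.17 with equal library totals, adjusted p = 0.979 with camera's direction lower), and Lss fell by 0.72.

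All 27 respiratory chain genes rose, by either adjustment (adjusted p = 2.57e-09, and adjusted p = 0.317 with an estimated correlation). Among them were Ndufv1 (1068 ± 67.9 to 2229 ± 415), Sdha (0.53) and Uqcrfs1 (0.76). Changes with LCAT followed transcript length across genes (Spearman rho -0.40), with a median of 0.44 in the shortest of 8 length classes and -0.44 in the longest. With length and GC content smoothed out, 23 of the respiratory chain genes were higher and 0 lower, with a median of 0.39. Glycolysis and glucose transport genes fell in 13 of 23 cases and rose in 3, by either adjustment (median -0.45, and -0.74 with length and GC content smoothed out, adjusted p = 0.00297, and adjusted p = 0.257 with an estimated correlation), with the glycolytic genes Pfkp (2462 ± 87 to 156 ± 30.7) and Pkm (5146 ± 171 to 1081 ± 101.3) and the glucose transporter gene Slc2a1 (-3.10). Of 18 p53 targets, 12 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.000441, and adjusted p = 0.103 with an estimated correlation). These included the cell cycle inhibitor gene Cdkn1a (4084 ± 163 to 1554 ± 128), Tnfrsf10b (-1.89) and Eda2r (-2.33). Of 29 cell cycle genes, 2 rose and 1 fell (1 and 0 adjusted over the list alone), with Pcna at 0.48, a call lost once length and GC content were smoothed out, and the list did not pass (median 0.03, and -0.15 with equal library totals, adjusted p = 0.904). Tumour and oncofetal markers had 10 of 25 lower and 6 higher by either adjustment (median -0.28, -0.47 with equal library totals and -0.45 with length and GC content smoothed out, adjusted p = 0.177), with the fetal growth factor gene Igf2 going from 339.6 ± 42.1 to 32.1 ± 5.35.

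**Figure D3:**
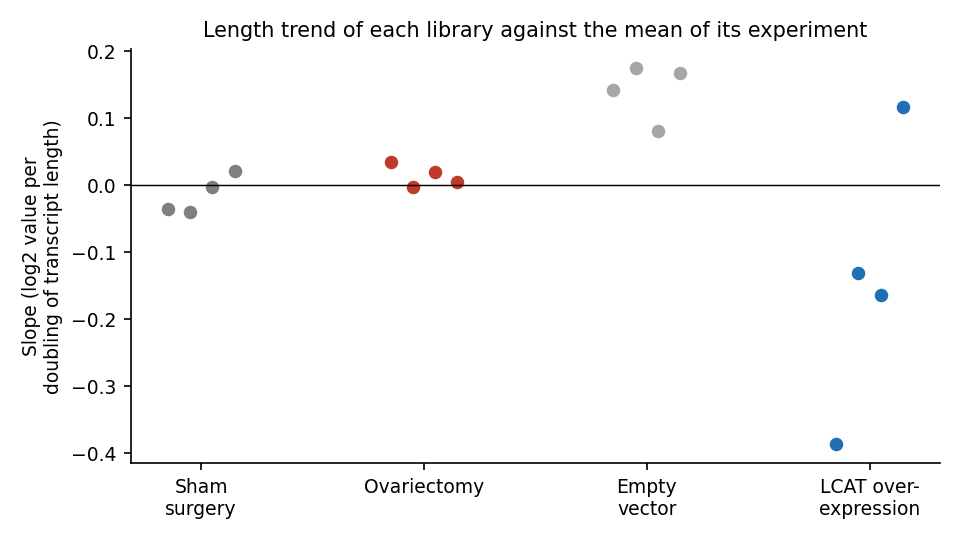
Slope of log2 values on transcript length, per doubling of length, for each library against the mean of the 8 libraries of its experiment, by group. Empty vector libraries ranged from 0.08 to 0.17 and LCAT libraries from -0.39 to 0.12.

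Matrix genes fell in 16 of 28 cases and rose in 3 (18 and 3 adjusted over the list alone; median -0.63, and -0.42 with length and GC content smoothed out, adjusted p = 0.000227, and adjusted p = 0.173 with an estimated correlation), with the collagen cross-linking gene Loxl2 (594 ± 43 to 156 ± 23.3) and Col4a2 (-1.28) lower and Lum higher (1.25). Interferon response genes fell in 7 of 24 cases and rose in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.0172, and adjusted p = 0.641 with an estimated correlation, and 0.162 without LCAT library 4). Among them were Ifih1 (-0.86), Rsad2 (-1.69) and Ifi44 (-1.45). The number lower was 4 without empty vector library 1 and 16 without LCAT library 1. The acute phase list had 9 of 24 lower and 2 higher (9 and 3 adjusted over the list alone; adjusted p = 0.0356, and adjusted p = 0.47 with an estimated correlation, 0.0735 without empty vector library 3 and 0.174 without LCAT library 4), with Serpina3n (24492 ± 733 to 8937 ± 307), Steap4 (-1.55) and the fibrinogen gene Fga (-0.89). With length and GC content smoothed out, 15 of the acute phase genes were lower (median -0.68 against -0.35 as deposited, and -0.53 with equal library totals, adjusted p = 0.000178). Antigen presentation genes rose in 7 of 15 cases and fell in 1, by either adjustment (median 0.45, 0.26 with equal library totals and 0.10 with length and GC content smoothed out, adjusted p = 0.0169, and adjusted p = 0.511 with an estimated correlation, and 0.0576 without LCAT library 1). These included H2-Aa (675 ± 64.4 to 1682 ± 320.2), Cd74 (1.28) and H2-DMb1 (1.27). Lists of NRF2 targets (median 0.19, adjusted p = 0.354), cytokines (0.31, 0.277), the unfolded protein response (-0.03, 0.232) and the circadian clock (-0.07, 0.605) did not pass. With equal totals their medians were 0.0 for NRF2 targets (4 higher and 4 lower), 0.13 for cytokines, -0.22 for the unfolded protein response and -0.26 for the clock. With length and GC content smoothed out they were -0.10 for NRF2 targets and -0.15 for the clock. The unfolded protein list passed with length and GC content smoothed out (median -0.30, adjusted p = 0.0309, 10 of 20 lower). Adjusted over the list alone, 7 of 24 NRF2 targets were higher and 3 lower, 7 and 4 of 20 cytokines, 2 and 8 of 20 stress genes, and 3 and 4 of 20 clock genes, the same counts as over all genes except for 6 higher cytokines. Single members of these lists that passed were Il1a (2.37), Chac1 (-1.27) and Usp2 (1.57).

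Markers of resident liver cells were higher with LCAT. Kupffer cell markers rose in 10 of 12 cases and fell in 2 (median 1.08, adjusted p = 0.00251, and adjusted p = 0.208 with an estimated correlation), with Cd5l going from 93.9 ± 26.6 to 749.7 ± 233, Csf1r (1.10) and C1qc (0.94). Endothelial markers rose in 8 of 12 cases and fell in 2 (median 1.38, adjusted p = 0.0179, and adjusted p = 0.47 with an estimated correlation, and 0.0552 without LCAT library 4), with Oit3 (3.11) and Gpr182 (2.22) higher and Cdh5 lower (-1.20). Stellate cell markers rose in 7 of 12 cases and fell in 0 (median 0.99, adjusted p = 0.00893, and adjusted p = 0.317 with an estimated correlation), with Dpt (1.83) and Cygb (0.74). Bile duct markers rose in 6 of 10 cases and fell in 1 (median 1.48, adjusted p = 0.0172, and adjusted p = 0.354 with an estimated correlation, and 0.0527 without LCAT library 4), with the keratin genes Krt19 (31.8 ± 9.88 to 409.8 ± 103) and Krt7 (2.64) higher and Spp1 lower (-1.50). The counts adjusted over the list alone were the same for these 4 lists.

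Monocyte (median 0.06, -0.12 with equal library totals and 0.26 with length and GC content smoothed out, adjusted p = 0.602), T cell (1.03, 0.47), NK cell (0.86, 0.707), B cell (1.65, 0.0737), neutrophil (1.43, 0.1), adipocyte (1.16, 0.322), erythroid (-1.52, 0.0717) and pancreatic (3.97, 0.602) lists did not pass. Adjusted over the list alone, 4 of 10 monocyte markers were higher and 3 lower (3 and 2 over all genes). By either adjustment, 0 of 4 T cell markers changed, while 1 of 3 NK cell markers were higher and 1 lower, 1 and 0 of 3 for B cells, 2 and 0 of 3 for neutrophils, 1 and 0 of 2 for adipocytes, 1 and 4 of 5 for erythroid cells and 2 and 1 of 3 for the pancreas. Of the markers listed, 4 of 12 were tested for T cells, 3 of 11 for NK cells and 3 of 11 for B cells. Tested were also 3 of 10 neutrophil, 2 of 7 adipocyte and 3 of 10 pancreatic markers. The medians of these lists do not stand for all their markers. The B cell list passed without empty vector library 4 (adjusted p = 0.0437), and the erythroid list without LCAT library 1 (0.0465) or 3 (0.0319). Single members that passed were Lyz2 (1.73), Klrb1c (-0.92), the plasma cell gene Jchain (2.74), S100a9 (1.43), Car3 (2.50) and Alas2 (1.66). The pancreatic gene Ctrb1 had 0 reads in the empty vector group and 56.8 ± 61.3 with LCAT, at least 76.0-fold higher. Its LCAT values were 143, 50.6, 33.4 and 0, and the bound was 37.5-fold without LCAT library 1. Its call (adjusted p = 0.0303) was lost without any library but LCAT 4 (0.0569 to 0.0818), and that of Klrb1c without empty vector library 2 (0.0772), 3 (0.0514) or 4 (0.0629), or with the replicate block. In the list of Xist and Y-linked genes, no gene was tested in the surgery groups, and only the 4 Y-linked genes, without Xist, in the vector groups. Of these 4, 3 fell and 0 rose, by either adjustment (median -0.67, and -0.44 with length and GC content smoothed out, adjusted p = 0.0393, and adjusted p = 0.317 with an estimated correlation, 0.0547 without empty vector library 3 and 0.0576 without LCAT library 1). Those that fell were Kdm5d (-0.96), Ddx3y (-0.54) and Uty (-0.79), of which Ddx3y and Uty lost their calls in a fit of all 16 libraries. The sex of the mice in the vector experiment is not given in the labels, but Y-linked genes were expressed in all of its libraries.

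**Figure D4:**
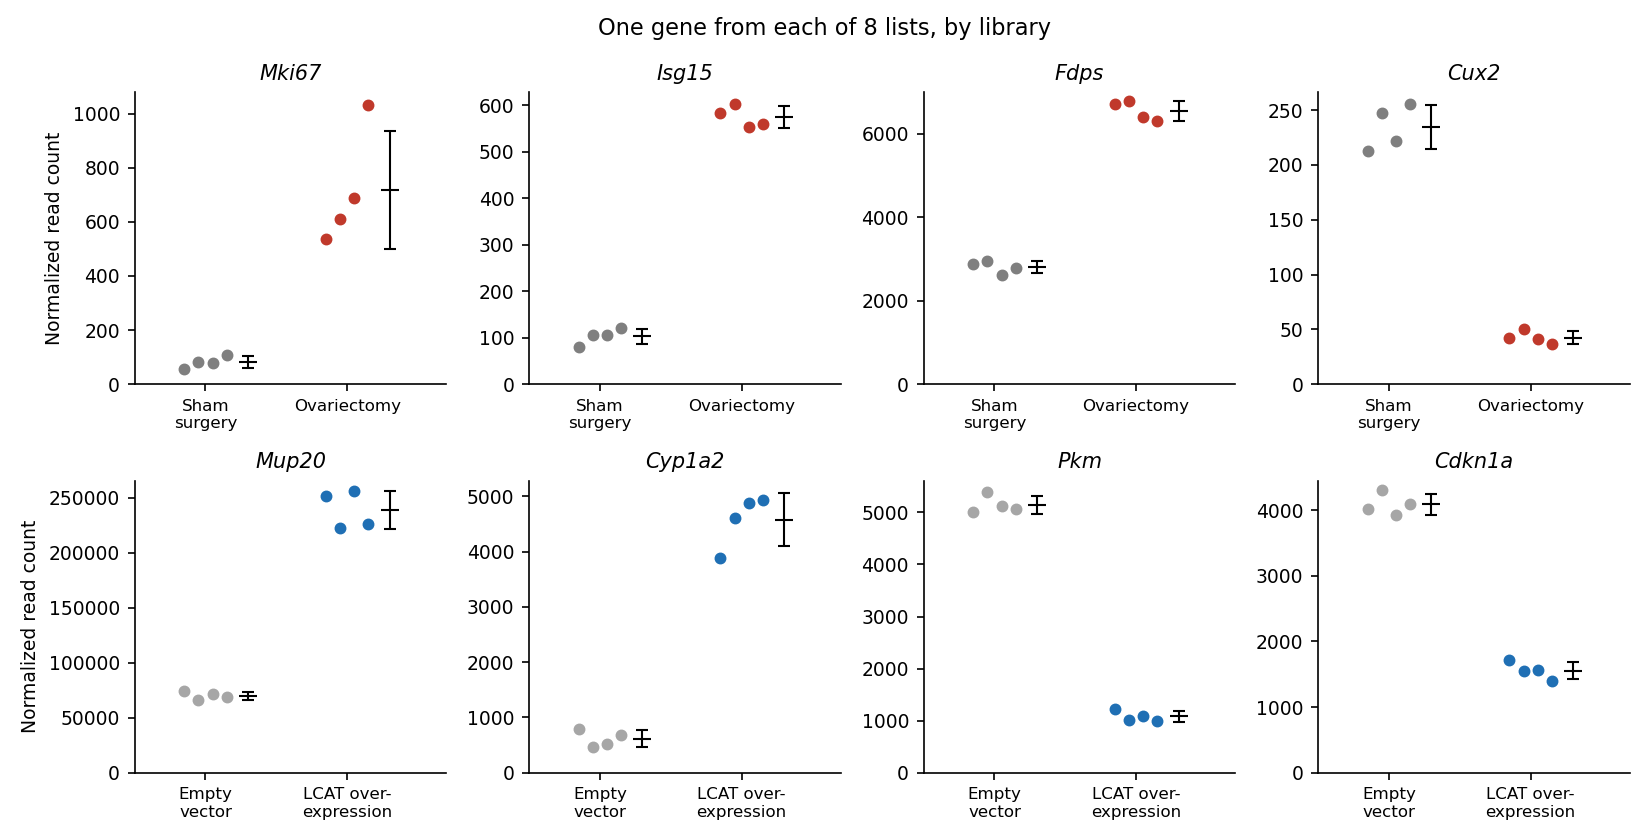
Normalized read counts per library of Mki67, Isg15, Fdps and Cux2 in the sham and ovariectomy groups, and of Mup20, Cyp1a2, Pkm and Cdkn1a in the empty vector and LCAT groups; points are libraries and lines with bars are means ± SD. Mki67 averaged 80.6 after sham surgery and 717 after ovariectomy, and Pkm 5146 with the empty vector and 1081 with LCAT.

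None of the 19 lists that passed after LCAT overexpression passed with an estimated correlation, against 8 of 23 after ovariectomy. With library totals set equal, the median of all genes shifted by -0.19 and 31.2% of 5758 called genes were higher, against 49.7% as deposited; limma called 2213 genes with LCAT libraries 1 and 4 alone against the 4 empty vector libraries. There the Y-linked list did not pass (adjusted p = 0.0596) and the erythroid list did (0.0279). The B cell (0.0326) and neutrophil (0.0475) lists passed with equal totals.

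The third comparison set both effects side by side, to ask whether LCAT overexpression moved the genes that ovariectomy moved, and which way. No library was shared between the experiments. The surgery mice were female, with 20 and 10 reads of Y-linked genes per group, against 9929 and 5551 in the vector groups. Effects in female liver were thus set against effects in tissue with a Y chromosome. Of 2263 genes called in both, 1526 (67.4%) moved in opposite directions, including Slc10a1, Hpd, Oit3, Sult2a1, Ndufv1, Spata20, Ifi44, Klrb1c and Spp1, whereas Cd74, Jchain and Lum rose in both. Lcat was also among the genes with opposite directions, but it is the gene that was overexpressed, so its rise is no response to LCAT. The LCAT calls of Lcat and Klrb1c were lost in several settings, as given above. In all, 867 genes were lower after ovariectomy and higher with LCAT, where independent lists would share 526, and 659 went the other way (498 for independent lists). Genes higher in both numbered 296 (482 for independent lists) and genes lower in both 441 (543).

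Across 12784 genes, which are not independent replicates, the 2 log2 fold changes had a Pearson r of -0.136 and a Spearman rho of -0.139. This correlation was not beyond what other splits of the vector libraries gave (permutation p = 0.257 over 35 splits), and 14 of the 35 splits gave a share of opposite or same directions as uneven. As sets, the genes higher after ovariectomy moved down with LCAT (2425 genes, median -0.16, fry adjusted p = 0.00478). The 100 of them with the smallest p did not pass (median -0.29, adjusted p = 0.0624). The genes lower after ovariectomy moved up (2643 genes, median 0.12, fry adjusted p = 0.00473). This direction depended on the scaling. With equal library totals for the LCAT fit, the lower set had a median of -0.07 (fry adjusted p = 0.758), with 650 of its genes called higher and 707 lower, and the higher set a median of -0.35 (1.05e-05). As deposited, the 100 genes of the lower set with the smallest p had a median of 0.65 (adjusted p = 8.36e-05). With equal totals both top sets passed, with medians of -0.47 and 0.47 (adjusted p = 0.0043 for both). fry tests whether a set moves on balance one way, and does not compare it with other genes.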

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

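The tests of explanations in this part were chosen after the results were seen. A library was listed where its gap to the nearest other, divided by the range of its group, exceeded 0.829; this held in 19 of 384 groups of 4 values of named genes or library measures, 4.95%, and chance gives about 1 in 20. In the sham group, library 4 stood above the others in Hpd (5722 against 5260.3 to 5327, gap 0.855). After ovariectomy, Myom3 was higher in library 4 (22.6 against 6.88 to 8.10, gap 0.922), and Lum was lower in library 3 (356 against 375 to 377, gap 0.871) and Klrb1c in library 1 (23.7 against 28.1 to 29.0, gap 0.832). In the empty vector group, library 3 stood apart in 5 genes. It was lower in Chac1 (149 against 161 to 162, gap 0.874), Eda2r (189 against 244 to 253, gap 0.863), Oit3 (19.7 against 48.3 to 51.5, gap 0.897) and Cdh5 (1001 against 1190.3 to 1213, gap 0.895), and higher in Spp1 (84682 against 67413 to 69260.1, gap 0.893). Other empty vector values apart were Aqp5 in library 1 (10.53 against 0, gap 1), Fga (130261 against 123186 to 123837, gap 0.908) and Krt19 (46.5 against 25.2 to 28.8, gap 0.831) in library 1, Loxl2 (659 against 568 to 576, gap 0.919) and Usp2 (176 against 339 to 359.95, gap 0.885) in library 2, and Vgf in library 4 (142 against 327 to 352, gap 0.878). With LCAT, Lcat was lower in library 4 (4531 against 5014 to 5106, gap 0.839), Sult2a1 higher in library 1 (57.6 against 24.7 to 28.6, gap 0.882), Fabp1 higher in library 3 (63589 against 51348 to 53227, gap 0.846) and Klrb1c lower in library 3 (8.35 against 15.5 to 16.5, gap 0.871).

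Sham and ovariectomy libraries 2 and 3 lay between libraries 1 and 4 in at least 91.2% of genes that differed at least 2-fold between these ends. Reads of the end libraries divided among the others would leave a residual at counting error, but the lowest residual was 1.94 times the counting variance, which argues against it. RNA mixed before library preparation may account for the line. The highest residual, 2.54, was above the 2.13 of the most alike pair of empty vector libraries, so this stays open. Mixing alone would not give the Esr1 value of sham library 3, which was 102 against 328 and 500 in libraries 1 and 4. Animals that differ along 1 tissue axis, which took 64.3% or more of the variance within either group, cannot be told apart from mixing. The labels do not say how libraries relate to animals. The gene-wise difference of sham library 4 from library 1 correlated with the effect of ovariectomy against sham libraries 2 and 3 (r = 0.418 across 11122 genes). LCAT libraries 2 and 3 also lay between libraries 1 and 4, in 95.8% and 94.96% of 1586 genes, with residuals of 2.90 and 4.51. If libraries of a group are mixtures, the p-values that rest on them are too small.

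Longer transcripts were lower after LCAT overexpression, and Lcat, with 1342 nt, is short. The slope on length, per doubling of length, spread over 0.0937 between the 4 empty vector libraries and over 0.504 between the LCAT libraries, with group means of 0.141 and -0.141. Recovery that depends on length and differs between libraries may account for part of this and cannot be told apart from an effect of LCAT on long transcripts (exact two-sided permutation p = 0.0571), because LCAT library 4, at 0.117, lay within the empty vector range. With length smoothed out, the respiratory chain median was 0.383 (quartiles 0.26 to 0.498), which argues against length as the whole cause. The change of Lcat went from 0.54 (SE 0.14) to 0.156 (SE 0.14) with length smoothed out and to 0.431 (adjusted p = 0.0375) with GC content, so its call ended because the difference shrank, as a length trend would have it.

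Markers of Kupffer, endothelial, stellate and bile duct cells were higher after LCAT overexpression. None of the 4 lists passed with an estimated correlation (adjusted p from 0.208 to 0.47). The endothelial and bile duct lists also did not pass without LCAT library 4 (0.0552 and 0.0527). The general hepatocyte genes were also higher (median 0.491, lower quartile 0.0363), which a lower share of hepatocytes alone would not give. With equal library totals, however, 12 of 24 were higher and 5 lower (median 0.304). With length and GC content smoothed out, 15 were higher and 4 lower (median 0.276). Higher expression per hepatocyte could also hide a lower share, so a lower share of hepatocytes stays open. Scaling is argued against, as the lowest of the 4 list medians was 0.809 with equal library totals. A lower share of tumour tissue could raise hepatocyte genes and resident cell markers together; the tumour markers had a median of -0.283 with members going both ways, so this cannot be told apart from a change in the cells themselves. The effect of LCAT on these cells was not tested separately.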

How the results depend on the processing

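The counts of other splits, fits on the end libraries, smoothing of length and GC content, and list and set tests with equal totals were chosen after the data were seen. Of the other splits of the 8 libraries, none reached the number of changed genes: 1 of 35 splits, the real one, gave as many after ovariectomy (5170, highest other 2) and after LCAT overexpression (5332, highest other 4). Each other split mixes treated and control libraries, so a group difference widens its spread and lowers its count. The low counts of the other splits are therefore no measure of chance. The smallest p that 35 splits can give is 0.0286, which does not exclude chance. It also holds only if the libraries are independent, which the labels do not say, and the surgery and LCAT libraries could be mixtures. For lists, 1 of 35 splits gave 23 or more after ovariectomy, but a split that mixes both groups still gave 22. After LCAT, 4 of 35 gave 19 or more (highest other 21), so chance is not excluded for that number. The number of lists passing at the preset correlation thus hardly sets the real grouping apart in either experiment. The set medians of genes higher (-0.163, highest other 0.152) and lower (0.117, highest other 0.0876) after ovariectomy were each matched by 1 of 35 splits, the real one. With equal totals the latter was -0.069 and did not pass, so its direction depends on the scaling. Asking for a log2 fold change of at least 1 left 1458 genes after ovariectomy (1000 higher, 458 lower) and 1764 after LCAT (898, 866), by construction. Equal totals gave 4441 higher and 1209 lower after ovariectomy. limma arrayWeights gave 8228 after LCAT (4064, 4164); the cause was not tested. End libraries, with fewer samples, gave 0 genes after ovariectomy (0 higher, 0 lower; 1688 at an unadjusted p below 0.05, 0 by edgeR) and 2213 after LCAT (1059, 1154). Lcat after ovariectomy passed in 22 of 23 alternatives (-0.78 to -0.50), not with end libraries (-0.77, adjusted p = 0.272). Lcat after LCAT passed in 18 of 23, and not with equal totals (0.35), end libraries (0.49) or smoothing (0.13). The male-biased, acute phase and stress response lists after ovariectomy did not pass with equal totals, nor the glycolysis list with a mean of at least 50. The lipoprotein and erythroid lists did not pass with that minimum, end libraries or smoothing. An estimated correlation left 8 lists after ovariectomy and 0 after LCAT. The top 100 genes higher after ovariectomy had a median of -0.29 with LCAT and did not pass. Reversed in direction (for lists, that of camera, which can differ from the sign of the median), without passing in either, were Esr1 after ovariectomy (equal totals 0.20, arrayWeights 0.69, edgeR 0.00036), its neutrophil list (mean of at least 50, -0.29) and, after LCAT, cholesterol synthesis (mean of at least 50 and replicate block 0.018, end libraries -0.0026, smoothing 0.026), acinar (mean of at least 50, -0.50), cell cycle (equal totals -0.15), NK cell (end libraries 0.18) and circadian lists (smoothing -0.15); the cause was not tested. Leaving out 1 library at a time gave 3677 to 6528 genes after ovariectomy (higher 1735 to 3220.0, lower 1863 to 3308; 18 to 25 lists; Lcat -0.78 to -0.70; Esr1 -0.52 to 0.49) and 3903 to 6828 after LCAT (higher 1928 to 3346, lower 1954 to 3482; 14 to 21 lists; Lcat 0.47 to 0.68). The most genes came without sham library 4 and without LCAT library 4. The ranges after LCAT were -0.0018 to 0.072 for cholesterol synthesis, -0.15 to 0.16 for cell cycle, -0.15 to 0.070 for circadian, 0.047 to 1.19 for NK cell and 1.47 to 5.30 for acinar lists, and -0.17 to -0.10 for the correlation of both effects. Other alternatives kept the direction and side of the threshold in 1330 of 1438 named gene tests after ovariectomy and 1312 of 1330 after LCAT, and in 219 of 250 and 222 of 257 list tests. Named gene calls lost numbered 105 and 18. Most named genes were picked from these same libraries for a small p or a large change, so their shares need not hold for all genes. The replicate numbers shared only a number: same-number correlations ran from -0.0585 to 0.0401 and from -0.0341 to 0.121, 0 and 1 of 4 libraries correlated best with their own number, and the replicate block gave 4339 and 4558 genes. A simulated log2 change of 0.5 was found in 12.1% of cases with ovariectomy settings and 7.6% with LCAT settings. The simulation changed 200 genes in independent libraries, whereas 5170 and 5332 genes were called here. These rates therefore need not hold for the data.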

Other observations

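The tests in this part were chosen after the results were seen. Called genes of the mitochondrial chromosome went in opposite directions in the experiments. Of 13 tested, 12 fell and 0 rose after ovariectomy (median -0.57, and -0.33 with equal library totals), and 7 rose and 0 fell after LCAT overexpression (median 0.43, and 0.25 with equal library totals). Cytosolic ribosomal protein genes, short and abundant, had a median of 0.28 after LCAT with 2 of 76 higher and 0 lower (camera p = 0.00387, and p = 0.668 with an estimated correlation). Their median was 0.09 with equal library totals and -0.17 once length and GC content were smoothed out. The 4 Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d ranged from 0 to 4.21 in the sham libraries, with 20 reads in all, and from 0 to 1.97 in the ovariectomy libraries, with 10 reads. In the vector experiment they ranged from 214 to 1332 with the empty vector and from 96.8 to 1096 with LCAT, which shows that tissue with a Y chromosome was present in all 8 libraries. Lcat itself was at almost the same level in the 4 sham libraries, with a coefficient of variation of 1.09%, below the 1.27% of counting error and at percentile 1.83 among 327 genes of like level, and at 21.6% in the empty vector group, percentile 94.4 of 656 genes. Esr1 varied by 51.3% between the sham libraries and 49.3% between the ovariectomy libraries.

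Several genes induced by low oxygen were lower with LCAT overexpression. Ndrg1 changed by -3.71 (limma adjusted p = 1.23e-06), Ankrd37 by -3.54, Ero1l by -3.48, Adm by -3.11, Egln3 by -3.06 and Hk2 by -3.12. Vegfa, the angiogenic growth factor gene, changed by -1.44 (adjusted p = 0.000257). Against the pattern, Angptl4 (1.02) and Higd1a (0.48) rose, Car9 went from 14.3 ± 4.65 to 52.3 ± 30.6 (1.54, adjusted p = 0.0675), and Pdk1 was at 0.05 (adjusted p = 0.808).

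Of 28 hypoxia response genes tested with LCAT overexpression, 18 were lower and 2 higher. After ovariectomy 11 of 27 were lower and 4 higher (median -0.40, -0.16 with equal library totals and -0.53 with length and GC content smoothed out). These genes were chosen after their values were seen, so no test of them as a list is given. Oxygen was not measured, and hypoxia genes are also set by growth factor signalling and by how much tumour a piece of tissue holds, so the values do not say what lowered them.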
